A study of Mus musculus with 6 samples.

How the data were processed

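RNA from lineage-negative, c-Kit-positive, Sca-1-negative marrow cells of Hes1-GFP mice was profiled on Affymetrix arrays, 3 from GFP-positive and 3 from GFP-negative cells. Per the labels, 5 ng of total RNA per sample was amplified with a NuGEN Ovation kit and labelled with biotin. The deposited values are probe set intensity values on a linear scale, made by the authors with RMA according to the submitters' processing notes. The RMA version and settings, and how the values returned to a linear scale, are not given in the sources used here. Values ran from 4.27 to 24551, with 0 missing and 0 below a floor of 1, and no detection calls were used.

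Values were taken to the log2 scale without further normalization. Of 45101 probe sets, 64 array controls were left out and 45037 were tested. Gene names came from GEO's platform annotation, which gives 1 gene for 34945 tested probe sets, several for 932 and none for 9160. Of the 1-gene probe sets, 34741 matched the RefSeq gene table of assembly GRCm38.p6 by gene ID with the same symbol and 204 were not matched. That table was used for names only, so no coordinates are given. A gene was represented by its probe set of highest mean over all 6 arrays, which gave 18193 genes, and 9010 genes had several probe sets. For 19 genes, probe sets were called in both directions. Calls of a gene's other probe sets are given below only for some genes.

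GFP-positive and GFP-negative arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided moderated statistics, no covariate), with Benjamini-Hochberg adjustment over all 45037 probe sets and a threshold of 0.05 on the adjusted p. The prior had 2.38 degrees of freedom and the total was 6.38. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 29 lists, with an estimated correlation as an alternative. Camera compares a list with all other genes, whereas fry tests whether the genes of a list move on balance in 1 direction. The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined.

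Named genes were Hes1, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with groups that did not overlap, and up to 4 members of each list with the largest absolute change among those past the threshold, or the 2 members of highest mean where fewer than 2 passed. Lists given mainly as counts have fewer names. Other genes were named after their values were seen, as stated beside them.

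The lists covered Notch targets, the Notch pathway, erythroid regulators, erythroid structural genes, heme synthesis and iron, megakaryocytes, early granulocytes, late neutrophils, monocytes with macrophages and dendritic cells, stem and multipotent cells, B cells, T and natural killer cells, mast cells with basophils and eosinophils, stroma and endothelium, progenitor surface markers, cytokine receptors, DNA replication, mitosis, kinase inhibitors, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, glycolysis, cholesterol synthesis, interferon response, immediate early genes, p53 targets, the unfolded protein response and lysosomes. Further families were formed from gene symbols that share a stem, with at least 8 measured members, a choice made after the results had been seen. Some of the families are not reported here.

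Alternatives were the replicate number as a block, an intensity trend with robust priors, quantile normalization repeated, array medians subtracted, the brighter 22519 or brightest 11260 probe sets, a fold floor of 1.5 (limma treat), array quality weights, other probe sets for a gene, other list tests, and leaving out each array. Leaving out both arrays with immunoglobulin signal was added after the data were seen. The labels number the replicates without saying that numbers pair. The arrays were treated as unpaired.

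The procedure was tested on simulated data of the same size and spread, with 200 changed probe sets in each of 5 simulations of the GFP-positive against GFP-negative comparison over 45037 probe sets. It recovered 0.896% of changes of 0.5 on the log2 scale, 36.4% of changes of 1 and 77.9% of changes of 2, and 4.98% of 402 calls were false. The adjustment is stricter where few probe sets change, and 6312 passed the threshold in the real data against 200 changed here. These shares are therefore not the sensitivity in the real comparison. Of 25 lists shifted by 0.5 the procedure called 25, and of 75 unshifted lists it called 1. The simulated noise was independent between probe sets, so these list counts do not show the error of camera where genes are correlated. In the real data the estimated correlation ran from -0.035 for cholesterol synthesis to 0.49 for oxidative phosphorylation genes. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.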

Results

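Gene expression was measured in mouse bone marrow progenitors sorted by a Hes1-GFP reporter, in which green fluorescent protein marks transcription from the Hes1 locus, a target of Notch signalling. The cells came from 6-week-old male mice carrying 1 reporter allele and were lineage-negative, positive for c-Kit and negative for Sca-1, the surface phenotype of myeloerythroid progenitors. There were 2 groups, GFP-positive and GFP-negative, with 3 Affymetrix arrays each. The labels do not say whether the arrays come from separate animals, and the number of arrays limits the precision of every value. The median intensity of an array lay between 59.9 and 64.9 and its mean between 749 and 754.

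The comparison of GFP-positive with GFP-negative arrays asks which genes differ between progenitors with and without reporter activity. GFP-positive cells had higher signal for erythroid genes such as Epor, the erythropoietin receptor, and Klf1, an erythroid transcription factor. They had lower signal for granulocyte and monocyte genes such as Csf1r and Irf8, and for genes of multipotent progenitors such as Flt3. Hes1 itself rose 2.40-fold, from a log2 intensity of 5.88 ± 0.14 to 7.15 ± 0.04 (SD, n = 3 each; limma adjusted p = 0.00141), and was higher in 3 of 3 GFP-positive arrays than in any GFP-negative array. Whether the probe set also measures transcripts of the reporter allele is not given in the sources used here. The cells were sorted on this reporter, so the rise of Hes1 serves as a check of the labels.

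Of 45037 probe sets, 2860 were higher and 3452 lower in GFP-positive arrays (limma, Benjamini-Hochberg adjusted p under 0.05), so that 45.3% of the calls were higher. With the array medians subtracted, 61.5% of the calls were higher. In all 6312 calls the 3 arrays of a group lay on the same side of the other 3. Groups did not overlap for 38.5% of all probe sets, against 10% by chance. Among 18193 genes, 1482 rose and 1805 fell, and 373 rose against 1059 that fell by at least 2-fold. The median log2 change was 0.67 in genes called higher and -1.14 in genes called lower. Over all genes it was 0.11, with 64.6% of genes above 0, and camera tests a list against the other genes. The higher count was 1257 without GFP-negative array 2, 1212 without GFP-negative array 3, 1396 without GFP-positive array 2 and 1555 without GFP-positive array 3. The lower count was 2300 without GFP-negative array 2 and 2192 without GFP-negative array 3. Without both arrays with immunoglobulin signal (GFP-negative array 3 and GFP-positive array 1), 681 were higher and 1652 lower, a setting added after the data were seen. In it 35 of 112 named genes lost their call, and the value is given beside those that kept it without any 1 array. The p-values measure only the spread between these samples, which may be technical.

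**Figure D1:**
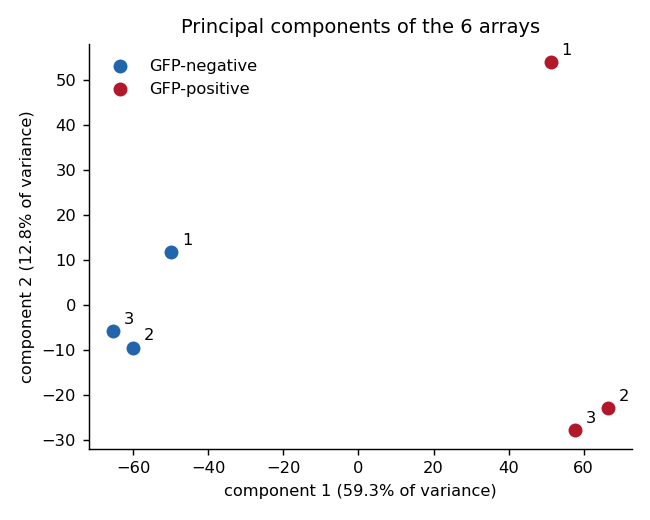
Scores of the 6 arrays on the first components of the log2 intensities, with the share of variance on each axis. The groups separate on the component with 59.3% of the variance, and GFP-positive array 1 stands apart from the other GFP-positive arrays on the component with 12.8%.

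Arrays of the same group correlated at r = 0.989 to 0.993 across probe sets, and arrays of different groups at 0.973 to 0.979. Probe sets are not independent replicates, so these are values without a test. The difference in intensity between 3' and 5' probe sets, a sign of RNA quality, was 0.58 ± 0.05 in GFP-negative and 0.63 ± 0.06 in GFP-positive arrays for beta-actin (SD of log2 values, n = 3 each). For Gapdh it was 0.61 ± 0.01 and 0.62 ± 0.01.

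The 10 largest rises included lymphocyte genes and solute carriers. Trgv1, a variable segment of the T cell receptor gamma locus, rose 17.2-fold (3.78 ± 0.20 to 7.89 ± 0.56, log2 intensity, SD, n = 3; adjusted p = 0.00113). Gzmb, a serine protease of cytotoxic granules, rose 15.9-fold (adjusted p = 0.000936), and Tox2, a transcription factor with a high mobility group box, rose 15.5-fold (adjusted p = 0.00124). Slc15a1, a peptide transporter, rose 13.7-fold. The related protease Gzma rose 8.17-fold, Bcl2l15 of the Bcl-2 family 7.13-fold and Trgv4, a further gamma segment, 6.23-fold. Slc6a20a, an imino acid transporter, rose 5.87-fold, the galactosyltransferase Ugt8a 5.79-fold and Slc37a3 5.76-fold. Adjusted p-values of these 10 genes ran from 0.000936 for Gzmb to 0.0124 for Gzma. Without both arrays with immunoglobulin signal, the adjusted p of Trgv4 was 0.0784. Limma called 2 of 3 probe sets of Trgv4 and 1 of 2 of Ugt8a higher.

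The 10 largest falls included receptors of lymphoid and multipotent progenitors. Btla, an inhibitory lymphocyte receptor, was 11.6-fold lower in GFP-positive arrays (8.51 ± 0.49 to 4.98 ± 0.30; adjusted p = 0.00126). Flt3, a receptor tyrosine kinase of multipotent and lymphoid progenitors, was 8.73-fold lower (10.92 ± 0.09 to 7.79 ± 0.55; adjusted p = 0.00154). Tlr7, a sensor of single-stranded RNA, was 8.03-fold lower (adjusted p = 0.000936). Fam135a was 12.4-fold lower, the sialyltransferase St8sia1 9.55-fold, Iqsec2, an exchange factor for Arf proteins, 8.33-fold, and Plcxd2 lay at 7.57 ± 0.24 and 4.57 ± 0.22. The zinc finger gene Tshz3 was 7.93-fold lower, the receptor phosphatase Ptpro 7.74-fold and Oosp1 7.40-fold. Adjusted p-values of these 10 genes ran from 0.000936 to 0.0282, the highest being that of Tshz3. Its adjusted p was 0.0746 without GFP-negative array 1, 0.0917 without GFP-negative array 3, 0.0744 without GFP-positive array 1 and 0.0827 without GFP-positive array 3. Without both arrays with immunoglobulin signal, the adjusted p was 0.0596 for Fam135a, 0.119 for St8sia1, 0.175 for Tshz3 and 0.0538 for Ptpro. Not all probe sets of these genes were called lower. Limma called 1 of 4 for Fam135a, 1 of 3 for St8sia1 and Tlr7, 1 of 2 for Plcxd2 and Ptpro, and 2 of 3 for Iqsec2. Folds against a group near the dim end of the range depend on the background of the arrays and are not bounds.

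**Figure D2:**
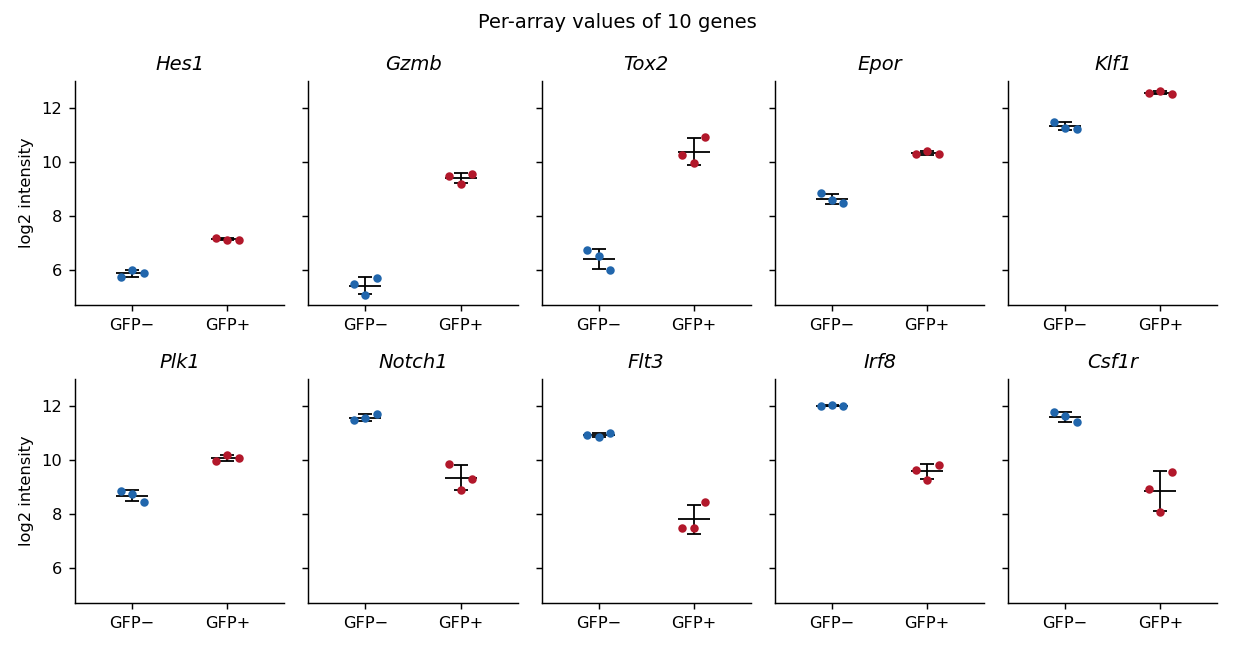
Log2 intensity of selected genes in each array, with points for the 3 arrays of each group and bars for the mean and SD. Hes1 lies at 5.88 ± 0.14 in GFP-negative and 7.15 ± 0.04 in GFP-positive arrays.

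Genes of red cell development were largely higher in GFP-positive cells. Of 25 measured erythroid structural genes, 18 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 change of 0.99. They included Sphk1, a sphingosine kinase, at 3.55-fold, Epb42, a membrane skeleton protein, at 3.31-fold, the Kell blood group antigen Kel at 3.20-fold and the adducin Add2 at 3.19-fold (adjusted p from 0.000936 for Sphk1 to 0.0150 for Epb42). The list moved relative to all other genes (camera adjusted p = 3.36e-10; adjusted p = 0.123 with an estimated correlation). Of 19 erythroid regulators, 12 rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.00295; adjusted p = 0.123 with an estimated correlation). Epor rose 3.26-fold (8.64 ± 0.19 to 10.35 ± 0.07; adjusted p = 0.00118) and Klf1 2.36-fold (11.32 ± 0.15 to 12.56 ± 0.05; adjusted p = 0.00166). Trim10 rose 2.25-fold and the repressor Gfi1b 2.20-fold. The 3 that fell, identified after their values were seen, were Cited2 at -0.74, Nfe2 at -0.52 and Lyl1 at -0.50 on the log2 scale. Without GFP-negative array 2 the adjusted p of Nfe2 was 0.0503, and with 1 array left out Lyl1 kept its call only without GFP-positive array 1 (adjusted p up to 0.106).

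Genes of heme synthesis and iron uptake rose with them, 12 of 15 up and 1 down (12 and 1 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 4.30e-05; adjusted p = 0.228 with an estimated correlation). Slc25a38, a mitochondrial glycine carrier, rose 2.91-fold, the endosomal ferrireductase Steap3 2.87-fold and the iron transporter Slc11a2 2.55-fold (adjusted p = 0.00183, 0.00204 and 0.00171). Alas1, the housekeeping form of the first enzyme of heme synthesis, was 2.47-fold lower (adjusted p = 0.00405).

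Granulocyte and monocyte genes were lower in GFP-positive cells. Of 23 early granulocyte genes, 19 fell and 0 rose (20 and 0 adjusted over the list alone), with a median of -1.16 (camera adjusted p = 1.55e-14; adjusted p = 0.137 with an estimated correlation). Anxa3 was 3.96-fold lower, Csf3r, the receptor of granulocyte colony-stimulating factor, 3.74-fold, Igsf6 3.70-fold and Sirpa 3.34-fold (adjusted p from 0.00110 to 0.00297). Of 33 monocyte, macrophage and dendritic genes, 19 fell and 2 rose (19 and 5 adjusted over the list alone), with a median of -1.01 (camera adjusted p = 1.11e-08; adjusted p = 0.137 with an estimated correlation). Csf1r, the receptor of macrophage colony-stimulating factor, was 6.69-fold lower (11.59 ± 0.19 to 8.85 ± 0.74; adjusted p = 0.00530, and 0.0624 without both arrays with immunoglobulin signal). The transcription factor Irf8 was 5.37-fold lower (11.99 ± 0.02 to 9.57 ± 0.27; adjusted p = 0.00108), the protease Ctss 5.00-fold and Klf4 4.36-fold. The 2 that rose, named after their values were seen, were the dendritic cell factor Zbtb46 by a log2 change of 1.66 and Id2 by 1.02, and with 1 array left out Id2 kept its call only without GFP-positive array 2 (adjusted p up to 0.136).

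Late neutrophil genes were not called as a group: 3 of 17 fell and 0 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.276), and the median and mean were 0.10 and 0.12 while the test pointed lower. Lysozyme Lyz2 was 3.29-fold lower (adjusted p = 0.000936), the chemokine receptor Cxcr2 2.73-fold (adjusted p = 0.0203) and the histone deiminase Padi4 2.70-fold (adjusted p = 0.00560). The adjusted p of Cxcr2 was 0.0594 without GFP-negative array 3, 0.0604 without GFP-positive array 1 and 0.0650 without GFP-positive array 3. The granule gene Camp, named after its values were seen, had a log2 change of 2.05 with an adjusted p of 0.175 and varied within the GFP-negative group (8.57 ± 1.76).

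Of 18 mast cell, basophil and eosinophil genes, 7 fell and 1 rose (7 and 2 adjusted over the list alone), with a median of -0.86 (camera adjusted p = 0.000810; adjusted p = 0.123 with an estimated correlation). The basophil protease Mcpt8 was 4.33-fold lower, the beta chain of the high-affinity IgE receptor Ms4a2 3.61-fold and histidine decarboxylase Hdc 3.23-fold (adjusted p = 0.00793, 0.00166 and 0.00365; 0.0673 for Mcpt8 without both arrays with immunoglobulin signal). The mast cell chymase Cma1 rose 3.95-fold (adjusted p = 0.0262). Its adjusted p was 0.0747 without GFP-negative array 1, 0.0616 without GFP-negative array 2, 0.0811 without GFP-negative array 3 and 0.0632 without GFP-positive array 1. The eosinophil granule gene Prg2, named after its values were seen, did not pass (adjusted p = 0.210): its log2 intensity was 3.43 and 4.31 in GFP-positive arrays 1 and 2, 10.89 in GFP-positive array 3, and 9.69 to 10.98 in GFP-negative arrays.

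Genes of stem and multipotent progenitors were lower in GFP-positive cells, with 21 of 30 down and 1 up (25 and 1 adjusted over the list alone) and a median of -1.29 (camera adjusted p = 1.55e-14; adjusted p = 0.123 with an estimated correlation). Besides Flt3, the transcription factor Hlf was 5.04-fold lower, Meis1 4.66-fold and Cd27, a receptor of the tumour necrosis factor family, 4.26-fold (adjusted p = 0.00392, 0.00297 and 0.00108). Mllt3, named after its values were seen, rose by a log2 change of 1.53 (adjusted p = 0.00108). Of 28 cytokine receptor genes, 18 fell and 1, Epor, rose (23 and 2 adjusted over the list alone), with a median of -1.16 (camera adjusted p = 2.32e-12; adjusted p = 0.123 with an estimated correlation). Il6st and Il6ra, the chains of the interleukin-6 receptor, were 5.16-fold and 4.68-fold lower (adjusted p = 0.00180 and 0.00154).

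Among 16 genes of progenitor surface markers, 8 fell and 2 rose (11 and 4 adjusted over the list alone), with a median of -1.11 (camera adjusted p = 4.63e-05; adjusted p = 0.123 with an estimated correlation). The Fc receptors Fcgr2b and Fcgr3, which mark granulocyte-monocyte progenitors, were 4.95-fold and 3.31-fold lower (adjusted p = 0.00127 and 0.00256). Named after their values were seen, Cd55 rose by a log2 change of 1.20 (adjusted p = 0.00247) and Eng, a marker of erythroid progenitors, by 0.53, a call kept only without GFP-negative array 1 when 1 array was left out (adjusted p up to 0.147). Kit, on which the cells were sorted, had a log2 change of -0.25 (adjusted p = 0.138).

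**Figure D3:**
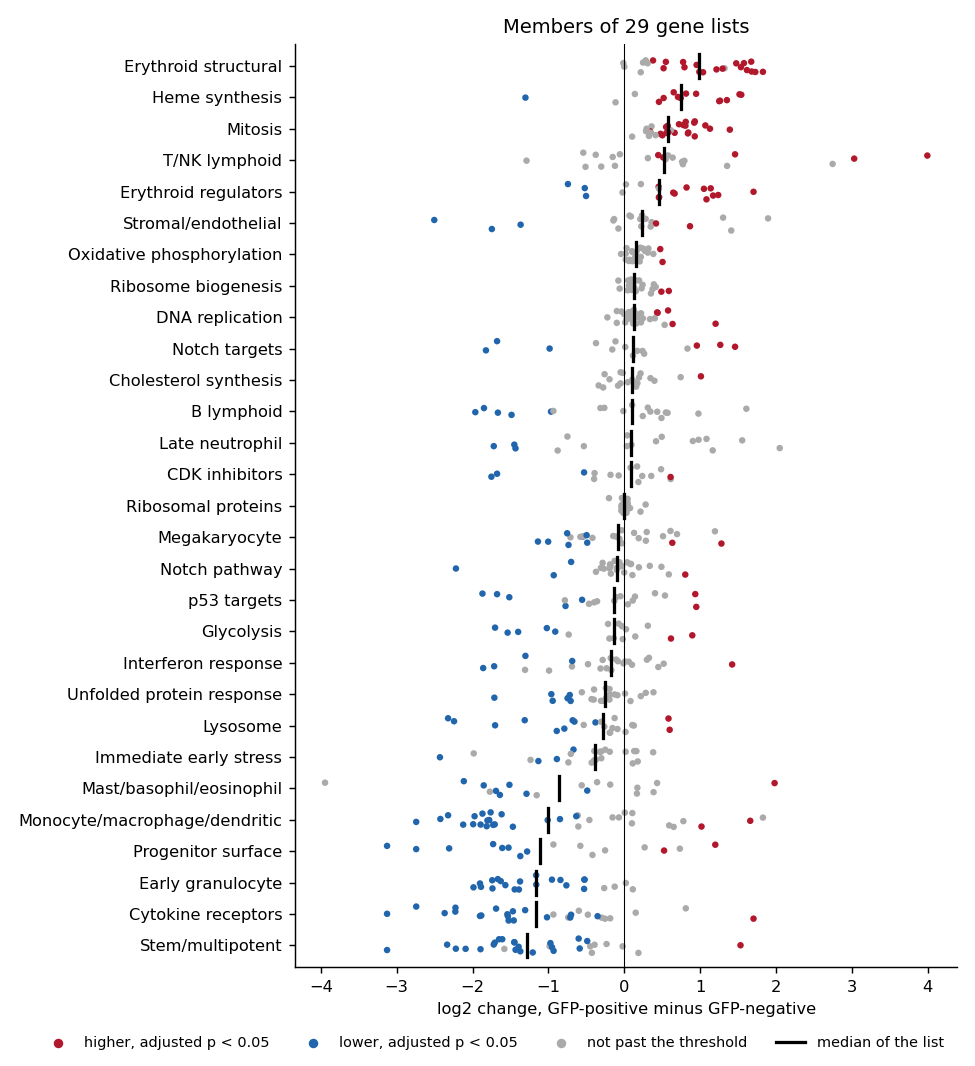
Log2 change of each measured member of 29 gene lists, GFP-positive minus GFP-negative, with a bar for the median of the list. Erythroid structural genes have a median of 0.99 and stem and multipotent genes one of -1.29.

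Notch genes changed in both directions. Of 15 Notch target genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.931). Among the 3 that rose was Hes1, on whose reporter the cells were sorted, so its rise is not a result separate from the sort. Besides Hes1, the transcription factor Gata3 rose 2.75-fold (adjusted p = 0.00358). Nrarp, a feedback regulator of Notch named after its values were seen, rose by a log2 change of 0.96. The survival gene Bcl2 was 3.54-fold lower (adjusted p = 0.00198) and the cell cycle inhibitor Cdkn1a 3.20-fold (adjusted p = 0.0158). Without GFP-negative array 2 the adjusted p of Cdkn1a was 0.0588, and without GFP-negative array 3 it was 0.0528. The third that fell, named after its values were seen, was Ccnd1 at -0.98, a call lost without any 1 of the 6 arrays (adjusted p from 0.0546 to 0.137). Of 28 genes of the pathway itself, 1 rose and 3 fell (1 and 3 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.0571). This list was called lower in 3 other settings, and over all settings its adjusted p ran from 0.0290 with camera on ranks to 0.582 with the probe set of highest variance. The receptor Notch1 was 4.65-fold lower (11.56 ± 0.12 to 9.34 ± 0.47; adjusted p = 0.00280) and Mfng, a glycosyltransferase of Notch receptors, 1.90-fold (adjusted p = 0.00810). The ligand Jag2 was 1.62-fold lower (adjusted p = 0.0131, and 0.0516 without GFP-negative array 3), and Psen2, a subunit of gamma-secretase, rose 1.75-fold (adjusted p = 0.00918, and 0.0758 without both arrays with immunoglobulin signal).

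Single lymphoid genes changed in both directions. Of 22 T and natural killer cell genes, 5 rose and 0 fell (10 and 1 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.0963; fry adjusted p = 0.00408). Camera called the list without GFP-negative array 3 (adjusted p = 0.0352) and without GFP-positive array 2 (adjusted p = 0.0371). The 5 were Gzmb, Gzma, Gata3, Cd8b1 and, named after its values were seen, Zap70. Cd8b1 changed by 0.51 on the log2 scale and lost its call without any 1 of the 6 arrays (adjusted p from 0.0628 to 0.104) and after quantile normalization (0.0772), and Zap70, at 0.45, kept its call only without GFP-positive array 1 (adjusted p up to 0.0952). Bcl11b, a T lineage factor named after its values were seen, had a log2 change of 2.75 with an adjusted p of 0.0566. The 13 genes of the T cell receptor complex and T cell surface on the list had a median log2 change of 0.31. Of 19 B lymphoid genes, 5 fell and 0 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.178; fry adjusted p = 0.0441), and the median was 0.10, near that of all genes, while the mean of -0.20 and the test pointed lower. The B cell receptor gene Cd79b was 3.60-fold lower, Cd72 3.17-fold and Dntt, which adds nucleotides in antigen receptor rearrangement, 2.80-fold (adjusted p = 0.00132, 0.00113 and 0.00392; 0.0505 for Dntt without both arrays with immunoglobulin signal). Rag2, named after its values were seen, fell by 0.97 on the log2 scale, a call kept only without GFP-negative array 2 when 1 array was left out (adjusted p up to 0.118). The heavy chain gene Ighm was 3.90-fold lower (adjusted p = 0.00213), but its adjusted p was 0.139 with the mean of its probe sets and 0.542 with the probe set of highest variance. Jchain, the joining chain of secreted antibodies, lay at a log2 intensity of 8.85 in GFP-negative array 3 and 8.65 in GFP-positive array 1, and at 3.64 to 4.08 in the other arrays.

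Of 26 megakaryocyte genes, 2 rose and 7 fell (5 and 9 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.0608). The list was called lower in 6 other settings, and without GFP-negative array 1 (adjusted p = 0.0376) and without GFP-positive array 1 (adjusted p = 0.0236). Plek, a substrate of protein kinase C in platelets, was 2.00-fold lower (adjusted p = 0.00347) and the transcription factor Mef2c 1.68-fold (adjusted p = 0.00537, and 0.0654 without both arrays with immunoglobulin signal). The platelet glycoprotein gene Gp5 rose 2.43-fold (adjusted p = 0.0280), a call kept only without GFP-negative array 2 or GFP-positive array 3 when 1 array was left out (adjusted p up to 0.0827), and Vwf, named after its values were seen, by a log2 change of 0.63 (adjusted p = 0.00913). Of 20 stromal and endothelial genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.882; fry adjusted p = 0.0345). The 3 that fell were endomucin Emcn at 5.67-fold, the adhesion molecule Pecam1 at 3.35-fold and Pdgfrb at 2.58-fold (adjusted p = 0.000936, 0.00108 and 0.00286). The adhesion molecule Vcam1 rose 1.82-fold (adjusted p = 0.0227, but 0.0630, 0.0684 and 0.0779 without GFP-negative arrays 1, 2 and 3, and 0.0910 with the probe set of highest variance), and Ibsp, named after its values were seen, by 0.42 on the log2 scale, a call kept only without GFP-positive array 1 (adjusted p up to 0.0992).

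Genes of mitosis were higher in GFP-positive cells. Of 29, 20 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 4.54e-09; adjusted p = 0.243 with an estimated correlation). The mitotic kinase Plk1 rose 2.62-fold (8.68 ± 0.21 to 10.07 ± 0.10; adjusted p = 0.00194), Aurka 2.19-fold, the spindle gene Aspm 2.10-fold and the phosphatase Cdc25c 1.91-fold (adjusted p = 0.0107, 0.00706 and 0.0205; 0.0725 for Aurka without both arrays with immunoglobulin signal). The adjusted p of Cdc25c was 0.0594 without GFP-positive array 1 and 0.0697 without GFP-positive array 2. Of 31 DNA replication genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.0571; fry adjusted p = 0.0118), among them cyclin E gene Ccne1 at 2.30-fold (adjusted p = 0.00592). This list was called in 9 other settings, fry among them, and by camera without GFP-negative array 1 (adjusted p = 0.0495) or GFP-positive array 1 (adjusted p = 0.0208). The other 4 were Tyms at 1.56-fold, Cdc6 at 1.49-fold, Rrm1 at 1.36-fold and, named after its values were seen, Rfc4 at a log2 change of 0.43. With 1 array left out, Tyms kept its call only without GFP-negative array 1 or GFP-positive array 1 (adjusted p up to 0.0659), Cdc6 only without GFP-positive array 1 (up to 0.0857), Rrm1 only without GFP-negative array 1 (up to 0.0977) and Rfc4 in no case (up to 0.124). With the mean of its probe sets, Tyms changed by 0.24 on the log2 scale (adjusted p = 0.152). Of 15 genes of cyclin-dependent kinase inhibitors and related brakes, 1 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.496), and the median was 0.08, near that of all genes, while the mean of -0.15 and the test pointed lower. Gadd45b was 3.37-fold lower (adjusted p = 0.00391), Btg1 1.44-fold lower (adjusted p = 0.0108) and Gadd45a 1.53-fold higher (adjusted p = 0.00954). Without both arrays with immunoglobulin signal, the adjusted p was 0.0617 for Ccne1, 0.0907 for Btg1 and 0.0780 for Gadd45a.

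Glycolysis genes were lower in part: 5 of 17 fell and 2 rose (6 and 3 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.00810; adjusted p = 0.394 with an estimated correlation, and 0.122 among the brighter 22519 probe sets). Pyruvate kinase Pkm was 3.26-fold lower, hexokinase Hk2 2.90-fold, the glucose transporter Slc2a1 2.64-fold and the phosphofructokinase Pfkp 2.03-fold (adjusted p = 0.00123, 0.00307, 0.00395 and 0.00347; 0.0612 for Slc2a1 without both arrays with immunoglobulin signal). The fifth, named after its values were seen, was the mutase Pgam1 at -0.91 on the log2 scale (adjusted p = 0.00298). The 2 that rose, named after their values were seen, encode other isoforms of these enzymes, Pfkm at 0.90 and Hk1 at 0.62 on the log2 scale, and Hk1 lost its call without GFP-negative arrays 2 or 3 or GFP-positive array 2 (adjusted p up to 0.0604). Lysosomal genes fell in 9 of 22 and rose in 2 (12 and 2 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 4.30e-05; adjusted p = 0.167 with an estimated correlation). The protease Ctsh was 4.74-fold lower, progranulin Grn 3.25-fold and the hexosaminidase subunit Hexa 2.48-fold (adjusted p = 0.0106, 0.00194 and 0.00338; 0.0881 for Ctsh without both arrays with immunoglobulin signal). The 2 that rose, named after their values were seen, were Ctsl and Galns at 0.60 and 0.58 on the log2 scale, calls kept only without GFP-negative array 1 when 1 array was left out (adjusted p up to 0.0699 and 0.0910). Of 26 oxidative phosphorylation genes, 2 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.15, against 0.11 for all genes (camera adjusted p = 0.0214; adjusted p = 0.603 with an estimated correlation). The camera adjusted p of this list was 0.0619 without GFP-negative array 3, 0.0560 without GFP-positive array 1, 0.123 without both arrays with immunoglobulin signal and 0.0598 with the probe set of highest variance. Its 2 calls, Cyc1 at 1.42-fold and Ndufs1 at 1.39-fold, were kept only without GFP-negative array 1 when 1 array was left out (adjusted p up to 0.127 and 0.111).

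Several stress genes were lower in GFP-positive cells. Of 24 genes of the unfolded protein response, 6 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 3.47e-05; adjusted p = 0.137 with an estimated correlation). The stress sensor Ern1 was 3.28-fold lower, Edem1 1.95-fold, Dnajb9 1.92-fold and Sdf2l1 1.68-fold (adjusted p = 0.00140, 0.00923, 0.00357 and 0.00836). Of 24 immediate early genes, which also respond to cell handling, 4 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.000557; adjusted p = 0.137 with an estimated correlation, and 0.184 among the brightest 11260 probe sets). Zfp36, which destabilises messenger RNA, was 5.39-fold lower and the phosphatase Dusp2 2.19-fold (adjusted p = 0.00298 and 0.00571). Ier3 was 1.85-fold and Ier2 1.59-fold lower; Ier3 lost its call without any 1 of the 6 arrays (adjusted p from 0.0547 to 0.114), and Ier2 without GFP-negative array 3 or GFP-positive arrays 2 or 3 (up to 0.0601). Of 24 interferon response genes, 4 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.0240; adjusted p = 0.394 with an estimated correlation, and 0.0982 without GFP-negative array 1 at the preset correlation). Its adjusted p was also 0.116 by fry, 0.0832 after quantile normalization, 0.231 among the brighter 22519 probe sets and 0.176 among the brightest 11260. The guanylate-binding protein gene Gbp3 was 3.28-fold lower and Oasl1 rose 2.68-fold (adjusted p = 0.00298 and 0.00374). Mx1 was 3.63-fold lower (adjusted p up to 0.0714 without GFP-negative array 3 or GFP-positive arrays 2 or 3) and Gbp2 2.47-fold, a call kept only without GFP-positive array 2 or 3 (up to 0.111) and lost after quantile normalization (0.0616), and Ifitm3, named after its values were seen, fell by 0.69 on the log2 scale. Of 19 p53 target genes, 2 rose and 5 fell (3 and 5 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.0585; fry adjusted p = 0.00877). The list was called lower by camera without GFP-negative array 1 (adjusted p = 0.0495) and without GFP-positive array 2 (adjusted p = 0.0375). The membrane gene Perp was 3.65-fold lower and the death gene Pmaip1 2.86-fold, and Gtse1 rose 1.93-fold (adjusted p = 0.00633, 0.00391 and 0.0133; 0.0883 for Gtse1 without both arrays with immunoglobulin signal). Cdkn1a fell too, as did Sesn1 and Trp53inp1, named after their values were seen, at -0.56 and -0.77 on the log2 scale. With 1 array left out, Sesn1 lost its call without GFP-negative array 2 or GFP-positive array 2 (adjusted p up to 0.0635), Cdkn1a without GFP-negative arrays 2 or 3 (up to 0.0588), and Trp53inp1 kept it only without GFP-negative array 1 or GFP-positive array 3 (up to 0.0779). The other rise, named after its values were seen, was Sesn2 at 0.94 on the log2 scale, a call kept only without GFP-negative array 1 or GFP-positive array 2 when 1 array was left out (adjusted p up to 0.0788).

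Camera did not call the remaining lists with the settings used throughout. Of 23 cytoplasmic ribosomal protein genes, 0 passed in either direction (limma; 0 and 0 adjusted over the list alone, 1 higher and 0 lower at an unadjusted p under 0.05), with a median of 0.00 and a mean of 0.02 while the test pointed lower (camera adjusted p = 0.628; fry adjusted p = 0.572). Rpl19 lay at 14.26 ± 0.01 in GFP-negative and 14.26 ± 0.02 in GFP-positive arrays, and Rpl27 at 14.13 ± 0.01 and 14.18 ± 0.01. Of 23 ribosome biogenesis genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.0701; fry adjusted p = 0.00510), and 21 of the 23 had a positive change, as did 64.6% of all genes. This list was called higher in 7 other settings, fry among them. The genes that rose were Rrp9 and Polr1b, by log2 changes of 0.59 and 0.49, and with 1 array left out Rrp9 lost its call without GFP-negative arrays 2 or 3 or GFP-positive array 2 (adjusted p up to 0.0738) and Polr1b kept it only without GFP-positive array 3 (up to 0.0933). Of 19 cholesterol synthesis genes, 1, Pmvk, rose and 0 fell (1 and 0 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.766; fry adjusted p = 0.0234). The median of all genes was also 0.11, and fry does not set a list against the other genes, so its call can restate that general shift. Pmvk, named after its values were seen, changed by 1.01 on the log2 scale (adjusted p = 0.00998), Hmgcs1 by -0.26 (adjusted p = 0.114) and Dhcr7 by 0.19 (adjusted p = 0.180). With an intensity trend both were called (adjusted p = 0.0178 and 0.0412), and Hmgcs1 was also called among the brightest 11260 probe sets (adjusted p = 0.0318) and with the mean of its probe sets (-0.42; adjusted p = 0.0274).

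Across the 29 lists, camera called 16 at its preset correlation, 5 higher and 11 lower, 0 with an estimated correlation, and the rotation test fry called 22. Since 64.6% of all genes had a positive change, a higher call by fry can restate that general shift. Lists share members, such as Flt3 on the stem, progenitor surface and cytokine receptor lists, so the called lists are not all separate results. Camera also called 5 to 15 lists in the other divisions of the 6 arrays into groups of 3, each of which sets 2 arrays of one reporter group and 1 of the other against the rest, so that part of the reporter difference stays in them.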

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

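The control probe sets on the arrays take no part in the comparison of genes, and the test on them was chosen only after the results for genes were seen. Of 64 controls, 11 were higher in GFP-positive than in GFP-negative arrays and 0 were lower (limma, Benjamini-Hochberg adjusted over the 64; 4 were lower at an unadjusted p under 0.05), for the 11 with all 3 arrays of a group above the other 3. The transferrin receptor, which imports iron, was higher by 1.19 on the log2 scale in its 3' probe set (adjusted p = 2.08e-05), 1.59 in the middle set (adjusted p = 7.33e-05) and 2.05 in the 5' set (adjusted p = 0.00164). The brightest probe set of the same gene, Tfrc, among those tested rose by 0.45 (adjusted p = 0.0314), a call kept only without GFP-positive array 1 when 1 array was left out (adjusted p up to 0.101), and its other probe sets by 1.11 and 1.63 (adjusted p = 0.00257 and 0.00141). Pyruvate carboxylase was higher by 0.98 in its 3' probe set (adjusted p = 0.000431), 0.47 in the 5' set (adjusted p = 0.0319), and 0.40 and 0.49 in the middle sets (adjusted p = 0.00164 and 0.0319). The 5' probe set of 18S ribosomal RNA was higher by 0.42 (adjusted p = 0.0247). The bacterial control Dap was higher by 0.35 in its 5' and 0.24 in its middle probe set (adjusted p = 0.0319 each), and Thr by 0.25 in its 3' set (adjusted p = 0.0478). Dap lay near the dim end of the arrays, at 3.44 ± 0.14 and 3.79 ± 0.10 in the 5' set (SD, n = 3 each).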

How the results depend on the processing

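Leaving out the arrays with immunoglobulin signal was the only alternative chosen after the data were seen. Of 112 named genes past the threshold, 0 changed sign in any setting and 91 kept the call without any 1 array, while 21 lost it without at least 1. The call was lost for 42 of the named genes with the fold floor, 35 without both immunoglobulin arrays and 10 with the replicate block. Hes1 stayed past the threshold wherever it was tested, from an adjusted p of 0.000928 among the brighter 22519 probe sets to 0.0302 without both immunoglobulin arrays; the brightest 11260 do not hold it. With replicate number as a block, 1969 probe sets were higher and 2872 lower, and Hes1 had an adjusted p of 0.0156. After group means were removed, arrays of the same number correlated at r = 0.0231, 0.0547 and 0.0191 across probe sets, each under 0.1, so the numbers were not taken as pairs. Still, 6 of 6 arrays correlated best with the array of their own number in the other group (other numbers -0.0428 to 0.0159), a hint from the data and not from the design. The higher count was 5218 with array medians subtracted, 348 with a fold floor of 1.5, 681 without both immunoglobulin arrays (2 arrays per group) and 1212 to 2243 without 1 array. The lower count was 1893 among the brightest 11260 (fewer probe sets tested), 954 with the fold floor, 1652 without both immunoglobulin arrays and 2192 to 3098 without 1 array. A stricter test or fewer arrays tend to lower a count. The counts without 1 array also differed by which array was left out. They were highest without GFP-negative array 1 (2243 higher, 2954 lower) or GFP-positive array 1 (2137 and 3098). These arrays had the lowest quality weights, 0.621 and 0.576, against 1.13 to 1.51 for the others. With such weights in the fit, 4083 were higher and 4121 lower. The cause of the difference between arrays was not tested. Subtracting array medians moved the median log2 change over all probe sets from 0.0888 to 0.166, a shift of every change that adds higher calls. The number of called lists was 0 with an estimated correlation, 22 by fry, 20 with the intensity trend and with array medians subtracted, 15 after quantile normalization and 16 to 18 without 1 array; the lowest within-group correlation was 0.977 among the brighter 22519, where the highest between groups was 0.946, and the cause was not tested. Of 16 called lists, 12 kept the call in every setting but the estimated correlation, and glycolysis, interferon, immediate early and oxidative phosphorylation genes did not. Of 13 uncalled lists, 9 gained a call in some setting other than leaving out 1 array, DNA replication in 9, ribosome biogenesis in 7, megakaryocyte genes in 6, T and natural killer genes in 4, the Notch pathway in 3, p53 targets in 2, and B lymphoid, cholesterol and stromal genes in 1 each. The test of Notch targets, never past the threshold, turned direction in 8 settings, with a mean log2 change of 0.0128 with the block and with the trend, 0.0159 after quantile normalization, 0.0898 with medians subtracted, -0.0270 with array weights, 0.0181 without GFP-negative array 1, -0.0832 without GFP-positive array 1 and -0.0625 without both immunoglobulin arrays. Without GFP-positive array 2 it did not turn, and the mean was 0.133. That of ribosomal proteins turned with medians subtracted (0.0952), fry (0.0182) and without both immunoglobulin arrays (0.0438), and that of stromal genes with medians subtracted (0.183), the probe set of highest variance (0.0453) and fry (0.106). Rpl19 changed sign, to 0.0145 after quantile normalization, 0.0741 with medians subtracted, 0.0147 without both immunoglobulin arrays, 0.00293 without GFP-negative array 3 and 0.00887 without GFP-positive array 1, but not without GFP-positive array 3 (-0.0144). Apart from the shift of Rpl19 with medians subtracted, the cause was not tested. Signal near background limits folds of dim genes.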

Other observations

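The tests on symbol families, on divisions of the arrays, on granzyme signal, on the excess of large falls and on immunoglobulin signal were all chosen only after the results were seen. Among 284 gene families that share a symbol stem, camera called 4 higher and 11 lower in GFP-positive arrays, against 0 to 7 families in the other divisions of the arrays and 0 with an estimated correlation (adjusted p = 0.752 or more). Genes of mitochondrial ribosomal proteins were higher in part, with 12 of 47 large-subunit genes and 8 of 29 small-subunit genes up and 0 down in either (camera adjusted p = 0.00128 and 0.0123; adjusted p = 0.805 with an estimated correlation for both). Of 11 aquaporins, 4 rose (camera adjusted p = 0.0212; adjusted p = 0.752 with an estimated correlation). They were the water channel Aqp1 of red cells by 0.78, Aqp9 by 0.75, Aqp11 by 1.52 and Aqp2 by 0.48 on the log2 scale. Aqp2 was dim, at 5.88 in GFP-negative arrays. The uncalled aquaporins lay at 3.43 to 6.04 there and changed by 0.09 to 0.44. The array medians were 5.90 to 6.02, so the family call rests in part on dim probe sets.

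Lower families included annexins and Smad genes. Of 11 annexins, which bind membranes with calcium, 6 fell and 0 rose (camera adjusted p = 0.0253; adjusted p = 0.752 with an estimated correlation), with Anxa2 at -1.70 and Anxa1 at -1.66. Of 8 Smad genes, transducers of transforming growth factor beta and bone morphogenetic protein signals, 6 fell and 0 rose (camera adjusted p = 0.0109; adjusted p = 0.752 with an estimated correlation), with Smad4 at -0.83 and Smad5 at -0.82.

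The 6 arrays can be divided into groups of 3 in 10 ways, so the share of divisions with a result as large cannot go under 0.1. For probe sets past the threshold, 1 of 10 divisions, the real one, gave as many (6312, against 0 as the highest of the others, where limma gave 699 to 1920 at an unadjusted p under 0.05). The other divisions put arrays of both reporter groups on each side, so the reporter difference widens the spread within sides and holds down the calls by limma. For gene lists called by camera, 1 of 10 gave as many (16, against 15 as the highest of the others).

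Among the 10 largest rises were Gzmb, Gzma, Trgv1 and Trgv4, whose median log2 change of 3.51 follows from that choice. Of 10 granzymes measured, limma called Gzmb and Gzma higher and 0 lower, and the other 8 changed by -0.26 to 0.34 on the log2 scale, 1 with an unadjusted p under 0.05. The T cell receptor gamma locus had only these 2 genes measured, with 2 of 3 probe sets of Trgv4 called higher, and camera did not call the T and natural killer list that holds both granzymes (adjusted p = 0.0963; fry adjusted p = 0.00408). For mature T cells in the sort, 13 T cell receptor complex and surface genes were taken from a list written before the data were examined. The choice of these 13, which leaves out Gata3 and Bcl11b of that list, was made after the results were seen. Their median change was 0.311 (95% bootstrap interval -0.30 to 0.55 over genes, which leaves out the spread between arrays). Cd3e lay at 5.15 and 5.95 and Thy1 at 5.95 and 6.26 in GFP-negative and GFP-positive arrays. These genes did not rise together as far as the granzyme and gamma genes above. Many were dim, so a small share of T cells cannot be told apart from its absence. Natural killer or innate lymphoid cells cannot be told apart from a change within progenitors, since the 5 natural killer genes of that list had a median of 0.577 (-0.51 to 1.36), with Ccl5 at 6.38 and 7.73 but Prf1 at 9.38 and 9.32, and they are too few. Of those genes, 4 of the 13 and 3 of the 5 lay above the median probe set in GFP-negative arrays, and 0 are on another list. Lineage depletion would be the gate that removes such cells, with antibodies not given in the sources used here, and expression of these genes by reporter-positive progenitors stays open as untested.

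More genes fell than rose by at least 2-fold in GFP-positive arrays, at a ratio of 2.84. The ratio was 2.15 with array medians subtracted and 2.29 after quantile normalization, so differences in centre left between the deposited arrays are not the whole cause. The array medians lay at 5.90 to 6.02 on the log2 scale. Subtracting them moved the median log2 change over all probe sets from 0.0888 to 0.166. That shift is small beside a 2-fold change, but it raised the higher calls of any size from 2860 to 5218. Whether the authors' own normalization shaped the ratio was not tested. The medians of the erythroid structural and megakaryocyte lists differed by 1.08 (95% bootstrap interval over genes 0.55 to 1.73). The median of erythroid regulators was 0.46, under the 0.99 of the structural list. These values do not decide whether a lower share of granulocyte and monocyte cells alone is the cause. Members of the megakaryocyte list such as Gata2 are also on lists of other cells, so the 2 lists need not rise alike. A broader difference in the make-up of reporter-positive and reporter-negative progenitors stays open as untested.

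Antibody transcripts stood out in GFP-positive array 1 and GFP-negative array 3, with Jchain in both, Igha at 10.49 in the former and an Ighm probe set at 11.15 in the latter. Probe sets at least 8-fold above the other arrays of the group, whatever their gene, numbered 12 in the former and 8 in the latter. Of these, 6 were shared (Fisher's exact test, 2-sided, p = 2.23e-21), against 0 shared by any of the other 14 pairs of arrays. The 2 arrays were singled out by the antibody signal they share, and related antibody probe sets are not independent. The p-value therefore restates that signal and does not decide on a separate local defect on each array. Of the excess probe sets with 1 gene, 5 of 6 and 4 of 5 were of immunoglobulin or J chain, as are 52 of 34945 tested. The other was Mboat7 in GFP-positive array 1 and Ebf1, a gene of the B lymphoid list, in GFP-negative array 3. Cells of the B lineage in general were not tested as a source. Antibody-secreting cells may be a source: 13 other plasma cell genes, listed after the antibody genes had been seen and before these 13 were, had a median excess of 0.0032 and 0.0117, but their level relative to antibody transcripts is unknown here, so a small share cannot be told apart from its absence. Lineage depletion could remove such cells, with antibodies not given in the sources used here. Reporter group was not tested as an explanation, since each group holds 1 of these arrays.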
